A study of Mus musculus with 25 samples.

How the data were processed

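RNA sequencing libraries were made from mouse mammary tumours that carry an activated Pik3ca allele together with a Cre-switched Cas9-EGFP reporter. Per the labels' protocols, tumours were dissociated with collagenase and then trypsin, and live GFP-positive cells were sorted before RNA extraction. The labels describe 25 tumours in 9 groups. Of these, 19 tumours in 7 groups received a lentivirus with Cre and a guide RNA, and 6 received an adenovirus with Cre under the Krt5 promoter, 3 of them Kdm6a wildtype and 3 Kdm6a fl/fl (both Kdm6a alleles flanked by loxP sites).

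The values used are raw counts per gene symbol, deposited by the authors without normalization. Per the submitters' processing notes, HISAT2 2.1.0, featureCounts and DESeq2 were used with the builds mm10 and GRCm38, which name the same assembly. The annotation release, the strand setting and the handling of reads shared between genes are not given in the sources used here, so counts of near-identical, overlapping or antisense genes are uncertain.

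The deposited count columns are headed only by running numbers, and no title, description or characteristic of any sample holds such a number. The study's design text puts the numbers 23 and 24 in the Cre-Lox experiment. The columns numbered 23 and 24 form a table of their own, and Kdm6a fl/fl replicates 1 and 2 are the only samples whose descriptions name that table. Both columns were therefore assigned to the Kdm6a fl/fl group, without deciding which is replicate 1, and are called library 23 and library 24. Assigning the other numbers to tumours would have rested on the order of the sample records. Those 23 columns were not used here, and no comparison with a control, or between guides, was made. The tests fixed before the data were examined, which included edgeR comparisons of every guide with the non-targeting guide and of Kdm6a fl/fl with wildtype tumours, were not run.

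Library 23 held 7733478 counts and library 24 held 14562103 counts. A count of 0, with 3 counts as the limit, allows up to 0.388 CPM (counts scaled to the library total) in library 23 and up to 0.206 CPM in library 24. These limits and all 95% intervals cover counting error only. Of 55304 rows, 26 carried a date in place of a gene symbol, as spreadsheet software writes for symbols such as those of the March and Septin families. These rows held 0.144% of the counts of library 23 and 0.143% of library 24, stayed in the totals and were not otherwise used.

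CPM was computed from the total of each library. Levels of different genes were also set on a common length scale as TPM, from the union of annotated exons in GENCODE M21 on GRCm38. The symbols of 53504 rows matched exactly 1 annotated gene, and these rows held 99.5% of the counts of library 23 and 99.4% of library 24. Levels are given as mean ± SD over the 2 libraries. Ratios between the libraries were computed as log2 of CPM + 0.5. Intervals of a fold between the libraries are exact (Clopper-Pearson) and intervals of a single level are Wilson intervals. The spread between the libraries was estimated with edgeR 4.0.16 in R 4.3.3 as a common biological coefficient of variation. On data simulated from the same means and totals, true coefficients of 0, 0.1 and 0.3 gave estimates of 0.00123, 0.1 and 0.294, over 13754, 13712 and 13588 genes respectively. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

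The 26 gene lists, with 369 genes, were fixed before the data were examined, and all 369 genes were in the table. The comparison of the 2 libraries over these lists, its settings and its alternatives were chosen after the data were examined. The alternatives were TMM scaling, a pseudocount of 2 CPM, members of at least 10 CPM, library 24 thinned to the total of library 23, removal of the trend with GC content and exon length, and leaving out either library. For each list with at least 5 members of 10 or more counts over both libraries, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins, drawn from 15703 genes. A list was called different when it lay below the 2.5 or above the 97.5 percentile. This percentile describes these 2 libraries and is not a p-value for a condition. The random lists draw genes independently, while genes of a real list may vary together, so the range can be too narrow for such a list. In data simulated for these libraries over 15760 and 15731 genes, a list of 14 genes with a planted log2 shift of 0 lay at percentile 35.0, and with a planted shift of 1 it gave a median of 0.97. Each was a single draw with counting noise only and with genes varying independently. The libraries differed by more than counting noise, so the simulation does not check the percentile limits for them.

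The rule for named genes fixed before the data were examined asked for adjusted p-values and separated groups, which a single group does not give. Adapted after the data were examined, it named the 6 targeted genes, the 2 members of each list with the highest mean CPM and, in each direction, the 10 genes with the largest ratio between the libraries among those with a mean of at least 4 on the log2 CPM scale. Clone names, predicted genes and mitochondrial genes were left out of that ranking. The 10 most abundant genes, and further list members that show the range within a list, were chosen after their values were seen. Some genes that the rule names are not reported here.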

Results

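The study asked how the loss of chromatin regulators alters mammary tumours driven by mutant Pik3ca. The data analysed here are 2 of the 25 tumour libraries it describes. Both came from Kdm6a fl/fl tumours started by adenoviral Krt5-Cre, which acts in keratin-5-positive basal cells of the mammary gland. Kdm6a encodes a histone H3 demethylase. Library 23 had 7733478 counts over genes and library 24 had 14562103. The first had 19926 genes with at least 1 count and the second 22131. The remaining 23 count columns could not be assigned to tumours from the labels and were not used here, so the values below describe Kdm6a fl/fl tumours and hold no contrast with Kdm6a wildtype tumours. The labels name both libraries as replicates and do not say whether they came from separate animals.

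Across the 13559 genes with at least 1 CPM in both libraries, log2 CPM correlated with Pearson r = 0.981 and Spearman rho = 0.985. Genes are not independent replicates, so no p is given. The common biological coefficient of variation was 0.156. The chi-square of the counts was 18.5 times its degrees of freedom, so the libraries differed by more than sampling noise and are not one library deposited in duplicate. Of 9736 genes with a mean of at least 10 CPM, 98.2% lay within 2-fold between the libraries, while 80 were more than 2-fold higher in library 24 and 93 in library 23.

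The targeted gene Kdm6a was detected at 60.0 ± 0.203 CPM (SD, n = 2). Library 23 had 463 Kdm6a counts, or 59.9 CPM with a 95% Wilson interval of 54.7 to 65.6, and library 24 had 876, or 60.2 CPM with an interval of 56.3 to 64.3. Kdm6a lies on chromosome X from 18162575 to 18279936 on GRCm38 and is protein-coding. The counts cover the whole gene, the labels do not say which exons the loxP sites flank, and transcripts that lack those exons would still be counted, so this level does not check the deletion. The genes targeted by guides in other tumours of the study were detected as well. Kmt2c, a histone methyltransferase gene on chromosome 5 from 25271798 to 25498783, stood at 149 ± 1.99 CPM. Setd2, another histone methyltransferase gene on chromosome 9 from 110532597 to 110618633, stood at 146 ± 11.1 CPM. Asxl2, a partner of the deubiquitinase Bap1 on chromosome 12 from 3426857 to 3506852, stood at 50.6 ± 4.74 CPM. Apc, on chromosome 18 from 34220924 to 34322552, stood at 135 ± 3.01 CPM, and Trp53, on chromosome 11 from 69580359 to 69591873, at 123 ± 14.4 CPM. Kdm6b, the autosomal relative of Kdm6a, had 323 ± 1.07 CPM, and Hcfc1, a cofactor of several chromatin complexes, had 161 ± 12.3 CPM. On the length-corrected scale, Kdm6b stood at 165 ± 2.51 TPM and Kdm6a at 25.4 ± 0.216 TPM.

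By CPM, which is not corrected for gene length, the most abundant transcript in both libraries was Igfbp5. It encodes an insulin-like growth factor binding protein and stood at 22414 ± 3649 CPM. The mean CPM of the libraries sets every order of levels given here, except where TPM is named. This order can differ from that within a library. Igfbp5 was followed by mt-Co1 at 7793 ± 112 CPM and the matrix protein gene Fn1 (fibronectin) at 7755 ± 3109 CPM. Next came the elongation factor Eef1a1 at 7369 ± 387 CPM and the matrix protein gene Postn (periostin) at 4719 ± 1066 CPM. Fn1 stood above mt-Co1 in library 23, at 9953 against 7872 CPM, and below Eef1a1 in library 24, at 5557 against 7643 CPM. Eef2, mt-Cytb, Fosb, Col1a2 and Trf completed the 10 most abundant genes by mean CPM. The order differed on the length-corrected scale, where Fn1, a long transcript, had 2362 ± 973 TPM and Trf had 3504 ± 265 TPM. Each library's own top 10, which need not be these genes, took 7.59% of the counts of library 23 and 6.36% of library 24. Mitochondrial transcripts made up 2.04% and 1.92% of the counts.

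Basal, luminal and milk protein genes were all expressed in these tumours. Of the 16 basal and myoepithelial genes, 15 had a mean of at least 10 CPM. The basal keratins Krt14 and Krt5 led the list at 3118 ± 28.4 and 2668 ± 200 CPM, the basal transcription factor Trp63 stood at 246 ± 70.0 CPM, and the contractile gene Acta2 at 362 ± 85.1 CPM. All 10 luminal keratin and junction genes exceeded 10 CPM, led by Krt8 at 928 ± 265 CPM and Krt19 at 668 ± 282 CPM. On the length-corrected scale, Krt14 reached 6298 ± 17.6 TPM, Krt5 4310 ± 273 TPM, Krt8 1680 ± 460 TPM and Krt19 1276 ± 525 TPM, so both basal keratins lay above both luminal keratins in each library.

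Of the 18 milk and alveolar genes, 11 had at least 10 CPM and 4 were under 1 CPM. Trf, which encodes transferrin, had 3278 ± 287 CPM and Mfge8, a milk fat globule protein gene, 1444 ± 13.2 CPM. The casein genes Csn1s1, Csn3 and Csn2 had 1187 ± 397, 745 ± 191 and 236 ± 81.9 CPM. In contrast, Lalba had 8.86 ± 0.0950 CPM, the whey acidic protein gene Wap 0.956 ± 0.477 CPM, and no count of Olah was found in either library. Luminal progenitor genes were present, with 11 of 12 at 10 CPM or more. Cd14 stood at 239 ± 21.1 CPM, the transcription factor Ehf at 227 ± 47.6 CPM, the receptor Kit at 176 ± 29.7 CPM and Elf5, a transcription factor of alveolar cells, at 83.0 ± 13.7 CPM. Of 14 hormone-sensing luminal genes, 13 reached 10 CPM. Ly6a led with 242 ± 7.34 CPM, and the prolactin receptor Prlr had 206 ± 164 CPM, with 322 CPM against 237 for Ly6a in library 24. That order within library 24 did not hold on the length-corrected scale, where Ly6a had 692 TPM and Prlr, a much longer transcript, 73.8 TPM. The estrogen receptor Esr1 had 50.5 ± 15.2 CPM. The progesterone receptor Pgr had 38.3 ± 23.9 CPM, with 21.5 CPM in library 23 and 55.2 CPM in library 24.

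Squamous differentiation was uneven across its list. Of 18 keratinocyte genes, 9 had at least 10 CPM and 5 were under 1 CPM. Sfn had 1003 ± 86.9 CPM and Krt16, a keratin of activated keratinocytes, 173 ± 25.0 CPM, while the cornified envelope genes Lor and Ivl had 1.01 ± 0.325 and 0.172 ± 0.243 CPM. Mesenchymal genes were abundant, with 14 of 15 at 10 CPM or more. Fn1 led the list by CPM, and Sparc followed at 3068 ± 955 CPM, while on the length-corrected scale Sparc stood above Fn1, at 2881 ± 930 against 2362 ± 973 TPM. Vim had 1317 ± 554 CPM, and the transcription factors Zeb1 and Snai2 had 19.1 ± 8.42 and 19.2 ± 0.392 CPM.

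**Figure D1:**
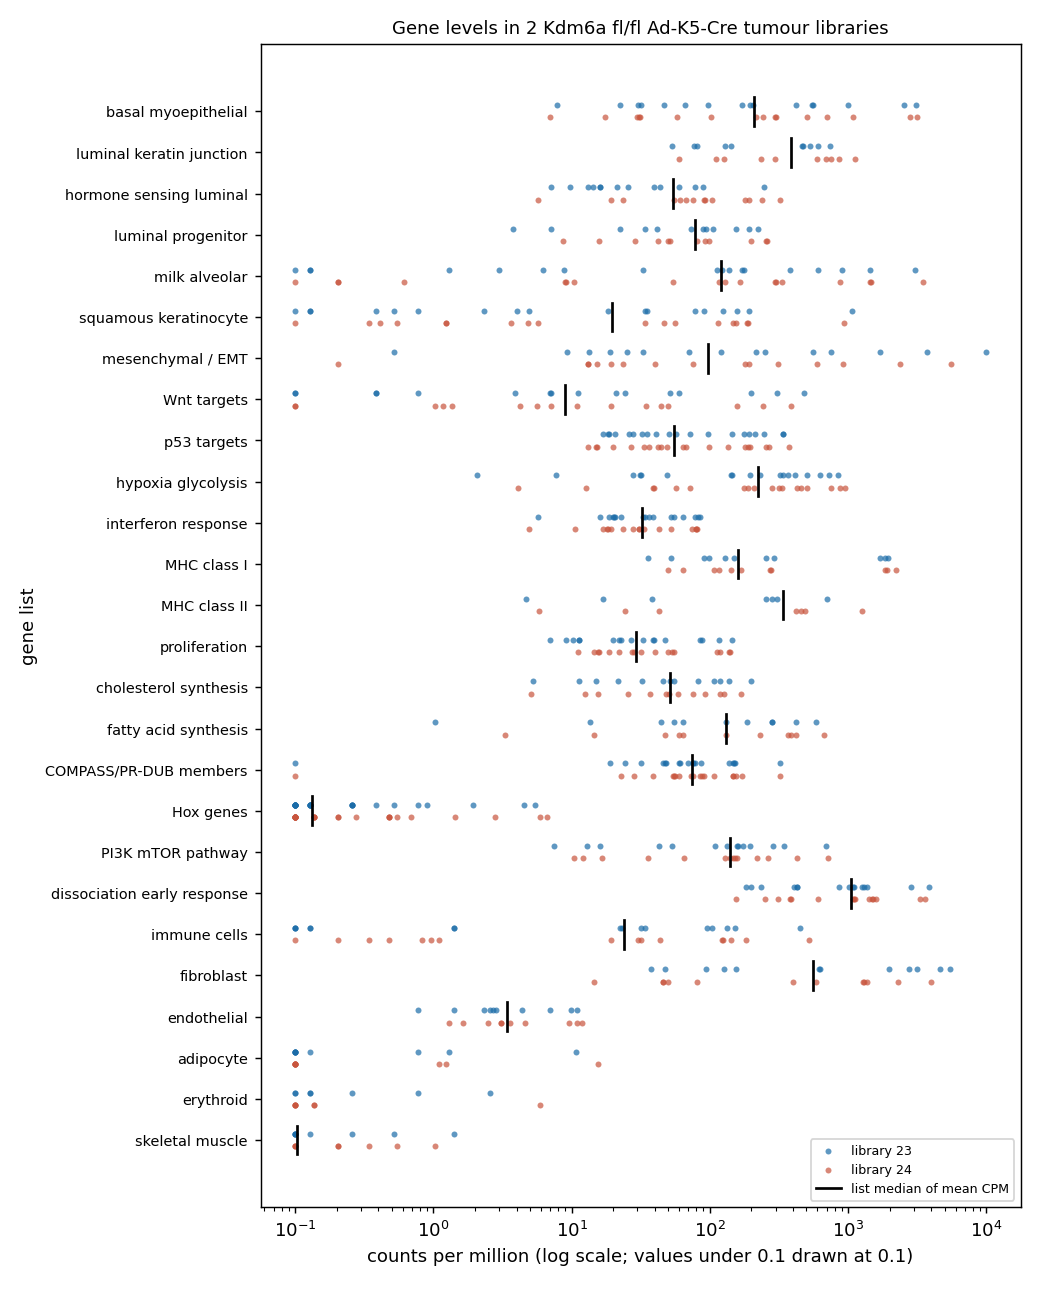
Levels of the members of 26 gene lists in CPM (x axis, log scale) in library 23 (blue) and library 24 (red), with 1 point per gene and library and levels under 0.1 CPM drawn at 0.1; black bars mark each list's median of the mean over both libraries where it is at least 0.1 CPM. Dissociation early-response genes have the highest list median at 1056 CPM, and the adipocyte, erythroid, skeletal muscle and Hox lists lie lowest.

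Dissociation early-response genes, a list fixed as a sign of handling, had the highest median level of all lists in tumours that were digested with collagenase and trypsin. All 15 exceeded 100 CPM, with Fosb at 3746 ± 168 CPM and Fos at 3090 ± 323 CPM, which ranked 8 and 12 among all genes by mean CPM. Wnt target genes were split, with 7 of 16 at 10 CPM or more. Wif1 and Nkd2, which encode Wnt inhibitors, had 433 ± 61.9 and 275 ± 45.2 CPM, whereas Axin2 had 6.37 ± 1.05 CPM and Lef1 0.778 ± 0.551 CPM. All 20 p53 target genes exceeded 10 CPM, led by Perp at 357 ± 24.5 CPM and the cell cycle inhibitor Cdkn1a at 305 ± 50.6 CPM. Hypoxia and glycolysis genes were led by Ldha at 899 ± 72.8 CPM and Eno1 at 805 ± 103 CPM. Among PI3K and mTOR pathway genes, the kinase gene Sgk1 had 703 ± 12.8 CPM and the regulatory subunit Pik3r1 386 ± 55.0 CPM. Of 17 proliferation genes, 16 had at least 10 CPM, with Pcna at 142 ± 2.97 CPM and Mki67 at 128 ± 15.3 CPM. In lipid synthesis, Scd2 had 632 ± 60.4 CPM and Fasn 422 ± 1.79 CPM. Of 13 cholesterol synthesis genes, 12 had at least 10 CPM, with a list median of 51.5 CPM.

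Antigen presentation genes of class I were abundant, with H2-K1 at 2083 ± 201 CPM and H2-D1 at 1875 ± 49.3 CPM. These 2 genes are close relatives and may share reads. Class II genes were led by Cd74 at 981 ± 396 CPM and H2-Aa at 400 ± 129 CPM. No interferon response gene reached 100 CPM, and Irf7 and Oasl2 led that list at 82.4 ± 2.89 and 80.7 ± 1.22 CPM. None of the 26 Hox genes reached 10 CPM, and the highest were Hoxb3 at 5.67 ± 0.336 CPM and Hoxb4 at 5.56 ± 1.46 CPM.

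Markers of other cell types were present to different degrees in the sorted cells. All 12 fibroblast genes had at least 10 CPM, with Postn at 4719 and Col1a2 at 3456 ± 1653 CPM, and the list took 1.97% of the counts of library 23 and 1.14% of library 24. Of 16 immune cell genes, 9 had at least 10 CPM. Lyz2 led with 486 ± 52.9 CPM and C1qa followed with 167 ± 21.9 CPM, both genes of macrophages, whereas the T cell gene Cd3e had 0.0343 ± 0.0486 CPM. Endothelial genes were low, with Flt1 at 11.4 ± 0.629 CPM and Pecam1 at 10.4 ± 0.680 CPM. Adipocyte genes were low apart from Lipe at 13.2 ± 3.43 CPM; Fabp4 had 1.20 ± 0.137 CPM and Adipoq had no count in either library. Erythroid genes were led by Hba-a1 at 4.25 ± 2.35 CPM, with 2.59 CPM in library 23 and 5.91 CPM in library 24. Alas2 followed at 0.457 ± 0.451 CPM, with 0.776 CPM in library 23 and 0.137 CPM in library 24. Skeletal muscle genes were led by Mylpf at 1.23 ± 0.277 CPM and Myh1 at 0.533 ± 0.0227 CPM.

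The 2 libraries differed most in hormone-sensing luminal and in fibroblast genes. Of the 14 hormone-sensing genes, 12 were higher in library 24, with a median log2 ratio of 1.51, above all 10000 random lists of matched level. Prlr was 3.58-fold higher in library 24 (95% exact interval 3.30 to 3.88), Cited1 4.18-fold (3.46 to 5.08), the osteoclast ligand gene Tnfsf11 4.66-fold (3.87 to 5.66), Wnt4 3.51-fold (3.02 to 4.09) and Calca, a calcitonin gene, 13.8-fold (11.3 to 17.1). Members with smaller ratios included the transcription factor genes Foxa1 (2.13-fold, 1.89 to 2.41), Esr1 (1.54-fold, 1.35 to 1.76) and Gata3 (1.32-fold, 1.20 to 1.45). Ly6a had a log2 ratio of -0.06, and Greb1 went the other way, 1.72-fold higher in library 23 (1.25 to 2.38). All 10 luminal keratin and junction genes were also higher in library 24, with a median log2 ratio of 0.63. The log2 ratio was 0.59 for Krt8, and Krt19 was 1.85-fold higher (1.78 to 1.92). Basal genes did not stand apart, with 9 of 16 higher in library 24 (6 under TMM scaling) and a median of 0.04 at percentile 39.5, whose sign turned to -0.07 under that scaling. The fibroblast list took the opposite direction to the luminal lists. All 12 members were higher in library 23, with a median log2 ratio of -0.97, below all random lists, and Col1a2 was 2.02-fold higher there (1.99 to 2.05). Of 14 mesenchymal genes with enough counts, 11 were higher in library 23, with a median of -0.56, and Fn1 was 1.79-fold higher (1.77 to 1.81).

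Of the 23 lists with enough counts, 10 lay above the range of random lists, 5 below and 8 within. The median of all 9736 genes with a mean of at least 10 CPM was itself 0.11 on this log2 scale, and -0.00048 with scaling by the trimmed mean of M-values (TMM), so list medians are read against matched random lists and not against 0. All 7 class II genes were higher in library 24, with a median of 0.67, and 16 of 17 proliferation genes were, with a median of 0.36. Squamous (0.44), luminal progenitor (0.34), hypoxia and glycolysis (0.30), milk and alveolar (0.26), dissociation early-response (0.21) and class I (0.17) lists also lay above the range, the last by a small margin at percentile 97.8, and inside it under 2 of 5 alternatives. Below it were the interferon response (-0.14), Wnt target (-0.07) and p53 target (-0.05) lists, by small margins for the last 2, at percentiles 2.47 and 1.24, and the p53 target list lay inside the range once library 24 was thinned to the total of library 23. Among the lists outside the range, medians that moved by over 1.5 times under an alternative were those of the smaller differences. TMM scaling gave 0.19 for hypoxia and glycolysis, 0.15 for milk and alveolar, 0.10 for dissociation early-response, 0.06 for class I, -0.15 for p53 target, -0.18 for Wnt target and -0.24 for interferon response genes. That scaling moves all ratios by nearly the same amount, those of the random lists as well, so these moves are not particular to the lists. With the trend with GC content and exon length removed, the medians were 0.29 for squamous, 0.20 for luminal progenitor, 0.20 for proliferation, 0.16 for hypoxia and glycolysis, 0.12 for milk and alveolar, 0.07 for dissociation early-response, 0.03 for class I, -0.16 for p53 target, -0.21 for Wnt target and -0.26 for interferon response genes. This removal subtracts the median of genes of like GC content or length. It therefore also takes out the overall offset between the libraries, and these moves are not the effect of the trend alone. Thinning library 24 gave -0.08 for interferon response, -0.12 for Wnt target and -0.0044 for p53 target genes. The Wnt target median was -0.29 over members of at least 10 CPM, and the squamous one was 0.26 over such members and with a pseudocount of 2 CPM. The squamous median of 0.44 was the ratio of Lor, which had 6 counts in library 23 and 18 in library 24. Of 15 squamous members with enough counts, 10 were higher in library 24. The most abundant ones, Sfn (-0.18) and Krt16 (-0.29), were higher in library 23. Within the range, besides the basal list, were the lists of immune cells (0.24, above the range under 3 of 5 alternatives), endothelial cells (0.19), chromatin complex members (0.16), Hox genes (0.14), fatty acid synthesis (0.12), cholesterol synthesis (0.01) and PI3K and mTOR pathway genes (-0.01). Medians of these lists moved or turned sign as well. TMM scaling gave 0.012 for fatty acid and -0.098 for cholesterol synthesis. With the GC content and length trend removed, the median was 0.012 for chromatin complex members and -0.023 for Hox genes. Thinning gave 0.017 for PI3K and mTOR pathway genes. With 1 library on each side, these ratios compare the libraries and no condition.

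**Figure D2:**
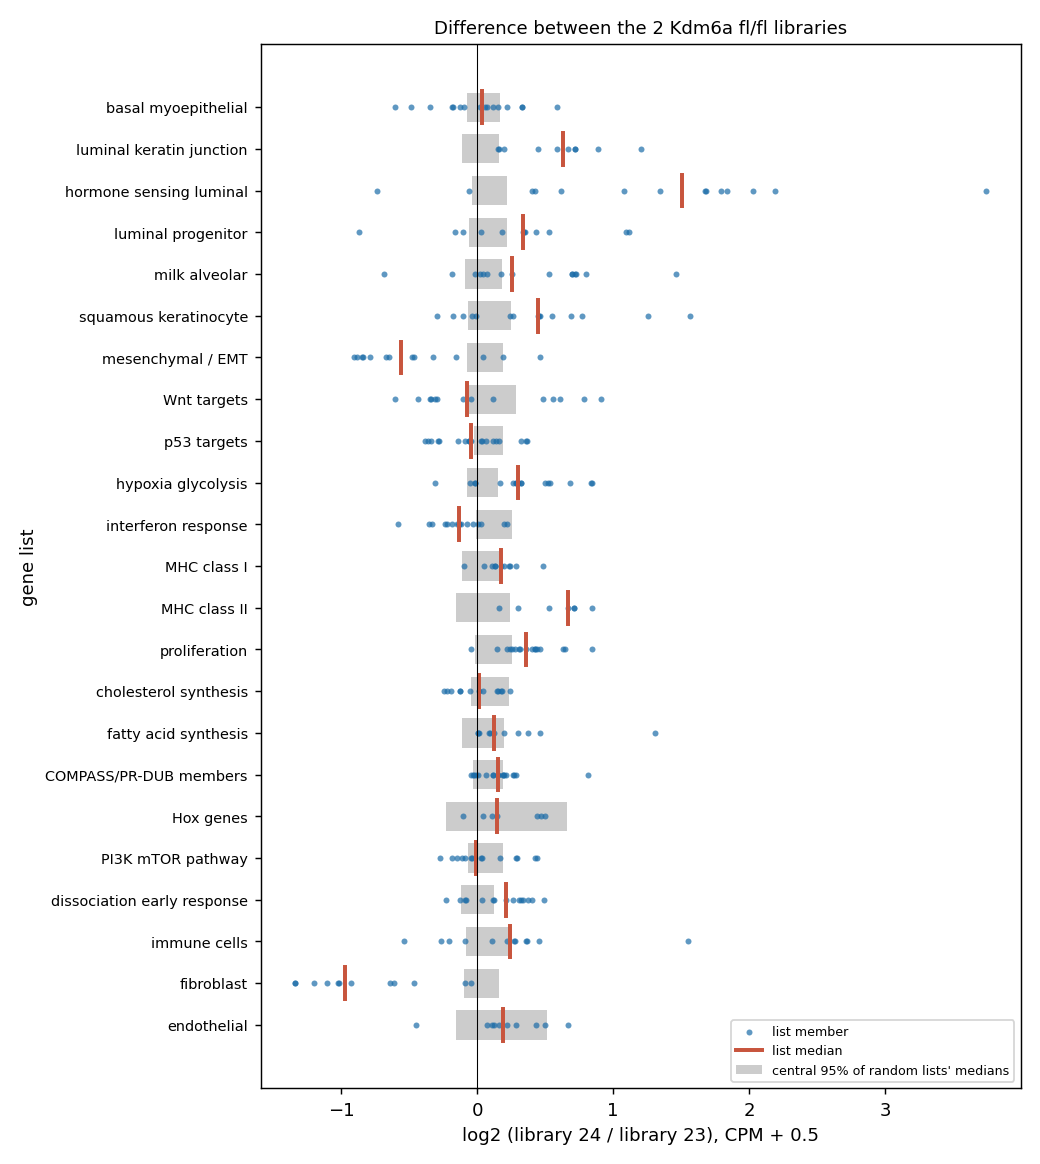
Log2 ratio of library 24 over library 23 (x axis, from CPM + 0.5) for list members with at least 10 counts over both libraries (blue points), with the list median (red) and the central 95% of medians of 10000 matched random lists (grey). The hormone-sensing list has the highest median at 1.51 and the fibroblast list the lowest at -0.97.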

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

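All alternatives here were chosen after the data were examined; those fixed beforehand concern comparisons between groups and were not run. No paired analysis was possible because only 1 group has columns that the labels assign, and its columns carry no replicate number. TMM scaling left all 23 list calls on the same side of the percentile limits. It shifts all ratios, those of the random lists included, by nearly the same amount, so it could hardly change a call. With library 24 thinned to the total of library 23, 22 calls held and the p53 target list moved inside the range, with a median log2 ratio of -0.0044. With a pseudocount of 2 CPM, 22 held and the immune list moved above the range at 0.24. With members of at least 10 CPM, 19 of 21 held, the class I list moved inside the range with an unchanged median of 0.17, and the immune list moved above it at 0.27; the Hox and endothelial lists had too few members left. After removal of the trend with GC content and exon length, 21 held, the class I list moved inside the range at 0.033 and the immune list above it at 0.12. The cause of these moves was not tested. No list that was called different took the opposite sign under these 5 alternatives. For the 82 genes named by the rule or as most abundant, the mean CPM under TMM scaling, or with either library left out, stayed within 1 SD of the value given; with 2 libraries the last of these holds by construction. Depth limits statements on the adipocyte, erythroid and skeletal muscle lists, which had too few counts for a ratio.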

Other observations

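The tests on Schwann cell markers, depth, and GC content with exon length were written down before their results were seen; those on epithelial share and fibroblast make-up were chosen after the result was seen. Of the 10 genes with the largest ratio in favour of library 23, Cdh19 (4.94-fold higher in library 23, 95% exact interval 3.81 to 6.45), Gfap (4.18-fold, 3.29 to 5.36) and the neurturin receptor gene Gfra2 (3.77-fold, 3.09 to 4.61) are known from Schwann cells. Retnla (5.22-fold, 4.18 to 6.56), Ccl6 (4.66-fold, 3.80 to 5.73) and F13a1 (3.98-fold, 3.44 to 4.62) are known from macrophages. Adam23, Slc35f1 and the neuronal tubulin gene Tubb3 were also among them. In the other direction the 10 genes were Calca, Agtr1a (7.68-fold higher in library 24, 6.61 to 8.97), Tnfsf11, Tmem56 (4.42-fold, 3.94 to 4.96), Zbtb16, Cited1, Slc35f3, Plac8, Prlr and Wnt4, of which 5 belong to the hormone-sensing list.

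The 8 myeloid members of the immune list had a median log2 ratio of 0.24 (range -0.21 to 0.36), against 0.67 for the 7 class II genes, a comparison picked because the class II list was high.

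The higher level of hormone-sensing luminal genes in library 24 was set against depth, GC content with gene length, and the share of epithelial cells. For depth, the prediction was a median log2 ratio near 0 once library 24 was thinned to the total of library 23. The median stayed at 1.49. Random thinning keeps the expected CPM of each gene, so it could hardly move a median at these levels and cannot test depth. A bias from GC content or gene length would end with that trend removed, and the median stayed at 1.40. A larger share of all epithelial cells would raise the basal list as well, but the hormone-sensing median exceeded the basal one by 1.47 and lay above every basal member, the highest of which stood at 0.59. The labels place both libraries in 1 group, so no explanation by genotype or treatment was tested. A larger share of hormone-sensing cells in that tumour, or higher expression per cell, may account for the pattern. The members' log2 ratios were uneven, from -0.74 to 3.74, and this spread was not tested against either.

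The lower level of fibroblast genes in library 24 kept its size after thinning (median log2 ratio -0.99). Thinning keeps the expected CPM of each gene, so this does not test depth. After removal of the GC content and length trend the median was -1.09, which argues against that trend as the cause. For tumours that differ only in the share of fibroblasts of one fixed make-up, the prediction was that the 12 members spread no more than other genes. It assumes that no other cells express these members, which was not tested, so a wide spread cannot tell share from state. The log2 ratios of the 12 members had an SD of 0.45, from -1.34 for Fap and Lum to -0.05 for Pdgfra and -0.09 for Dcn. This SD lay at percentile 92.95 among 10000 matched random lists (median SD 0.25, upper percentile limit 0.54), which neither excludes a difference in share alone nor speaks for it. What stays open is a lower share of fibroblasts in library 24, a change in fibroblast state, a mixture of fibroblast kinds, or expression of collagen genes by the tumour cells themselves. The GFP gate would remove fibroblasts that had not taken up Cre, but how fully it did so was not tested. Macrophage genes such as Lyz2, at a mean of 486 CPM, were found in the sorted cells.

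Schwann cells in library 23 were tested as a candidate source of the glial genes with 10 other markers. Their median log2 ratio was -0.45, below all 10000 matched random lists, and 8 of 10 were lower in library 24, but the median lay between the values set beforehand for and against this explanation. Foxd3 (-2.23), L1cam (-1.85) and Cmtm5 (-1.49) went with the glial genes, whereas the myelin gene Mbp (0.38) did not. The most abundant markers were Scn7a, at 67.0 CPM in library 23 and 39.0 in library 24, and Pmp22, at 57.9 and 38.8. Several of these markers are also expressed outside glia, and the test decides neither way. Glial cells without myelin, or glial genes switched on in tumour cells, may both give this pattern. The GFP gate would remove cells that had not taken up Cre, but how fully it did so was not tested.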
